A study of Rattus norvegicus with 20 samples.

How the data were processed

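The series compares 2 diets in adult male Sprague-Dawley rats, 10 animals each: an isocaloric modified AIN-93M diet with beef, and that diet with sodium nitrate added. Per the labels' protocols the animals had 1 week of habituation, were killed on day 35 of the diet with the order alternating between diets, and gave the right hippocampus for RNA. The series' own design text gives the diet as 4 weeks, and these statements differ. The nitrate dose is typed ambiguously in the design text and is not printed here. Per the labels, RNA was labelled with biotin using an Affymetrix kit that primes at the 3' end of transcripts. Groups and replicate numbers were taken from the sample titles, and sample numbers from the sample descriptions.

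The values used are the authors' deposited log2 values, 1 per probe set and array, made with RMA, with Partek also named and genome build rn6, per the submitters' processing notes. Versions are not given in the sources used here. RMA subtracts background, makes the arrays' probe distributions alike and summarises probes per probe set, so that a shift of all genes together would be removed. The log base is not stated, and log2 was read from the range of 3.33 to 13.31. Scanner files were not used here, so signal over background, detection and scan batches were not examined, and dim probe sets were kept. The annotation table gave 1 gene symbol to 15049 of the 23188 probe sets. The other 8139 were left unnamed, and any probe set with several symbols was counted among them. Symbols of list members that were not found were looked up among synonyms in a rat reference table of assembly GRCr8, of which no coordinates were used. No control probe sets had to be removed and 0 columns were left unmapped.

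Differences are nitrate minus beef. Each probe set was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 over all 20 arrays with no covariate, and p-values were adjusted by Benjamini-Hochberg over all probe sets with a threshold of 0.05. The prior carried 5.90 degrees of freedom. 41 gene lists with 1187 members, of which 1065 were measured, cover hippocampal fields, cell types, other tissues and pathways. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, using the probe set with the highest mean for the 10 genes that had more than 1. A list score is the mean over its genes of the log2 value minus the gene's mean over all arrays. Scores and the first 5 principal components were compared by two-sided permutation tests with 100000 resamples, or with all splits where a group had fewer than 10 animals, and adjusted over lists or components. Intervals are 95%.

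The lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined. The exceptions are alternatives or tests said to have been chosen afterwards, or after the pattern they address was seen. Genes are named when they pass the threshold, up to 12 per direction by size. As none passed, the 12 per direction with the smallest unadjusted p among genes above the median mean of 7.22 were named, together with 10 fixed genes and, as no member of a list passed over the list alone, the 3 genes of smallest p in each list. Genes named for animals that stand apart, for components and for separate clusters of values were chosen after their values were seen. The fit was tested on simulated data with 200 of 23188 probe sets changed in each of 10 runs, where it made 8.8 false calls per run on average. The list test was tested on 15037 genes and 41 lists in 20 simulated runs. With the preset correlation, all 20 runs without a diet effect called at least 1 list and as many as 10, and with the estimated correlation 0 of 20 did. A shift of 0.2 log2 units in the nitric oxide list was recovered in 20 of 20 runs by both. That list had an estimated correlation of -0.003, against 0.205 for endothelial and 0.193 for blood genes. Recovery in lists whose genes vary together was not tested. Alternatives covered normalization, dim probe sets, array weights, the variance prior, the probe sets of a gene, sample number, replicate number, a component of the residuals and the omission of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.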

Results

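Hippocampal transcripts were measured in 20 adult male Sprague-Dawley rats, an outbred laboratory strain, of which 10 ate a beef diet and 10 ate the same diet with sodium nitrate. Each animal gave 1 right hippocampus and 1 Affymetrix array, so that the values of a diet come from separate animals. The array reported 23188 probe sets, of which 15049 carried 1 gene symbol and stood for 15037 genes. The other 8139 probe sets are unnamed here. Array medians lay between 7.19 and 7.24 on the log2 scale. Interquartile ranges of the arrays ran from 3.01 in beef replicate 10 to 3.34 in nitrate replicate 1, so the distributions of probe set values were not fully alike. The correlation between any pair of arrays across probe sets, which are not independent replicates, lay between 0.983 and 0.995. The number of animals limits the precision of the comparison: the 95% interval of a difference between diets had a median half-width of 0.15 log2 units.

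The comparison of the diets asks whether added nitrate goes with a difference in gene expression in the hippocampus. No single gene separated the diets. Among moderately to strongly expressed genes, those with the smallest unadjusted p-values on the higher side included Abcb8, a mitochondrial ABC transporter (0.21 ± 0.06 log2 units, SE, n = 10 per diet; higher than the beef median in 9 of 10 nitrate animals), Rad54l2, a helicase (0.17 ± 0.05, SE, 10 of 10), and Pik3c2b, a phosphoinositide kinase (0.23 ± 0.07, SE, 10 of 10). On the lower side they included Gatd1 (-0.27 ± 0.08, SE; above the beef median in 1 of 10 nitrate animals), Cachd1, an auxiliary protein of voltage-gated calcium channels (-0.23 ± 0.07, SE, 0 of 10), and Mars1, the cytosolic methionyl-tRNA synthetase (-0.15 ± 0.05, SE, 1 of 10). None of these passed the adjustment for the 23188 probe sets.

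With limma, 0 probe sets passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.9999. A plain pooled-variance test without moderation also passed 0 probe sets. At an unadjusted p under 0.05, limma counted 552 probe sets, 320 higher and 232 lower on nitrate, against 1159 for an even spread of p-values, and the plain test counted 557. At an unadjusted p under 0.01 there were 78 against 232. The smallest unadjusted p was 0.0006. The median absolute difference was 0.04 log2 units, and for 99% of probe sets the 95% interval lay within 0.5 log2 units of 0. Simulated data had these animals' spread and 200 changed probe sets per run, with shifts of 0.25, 0.5 and 1 log2 units mixed. Limma recovered 33.4% of probe sets shifted by 0.25, 92.5% of those shifted by 0.5 and 99.8% of those shifted by 1. The Benjamini-Hochberg cut-off is looser when many probe sets pass, as in those runs. The rates therefore do not give the recovery of a few small shifts, which would be lower and was not tested.

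**Figure D1:**
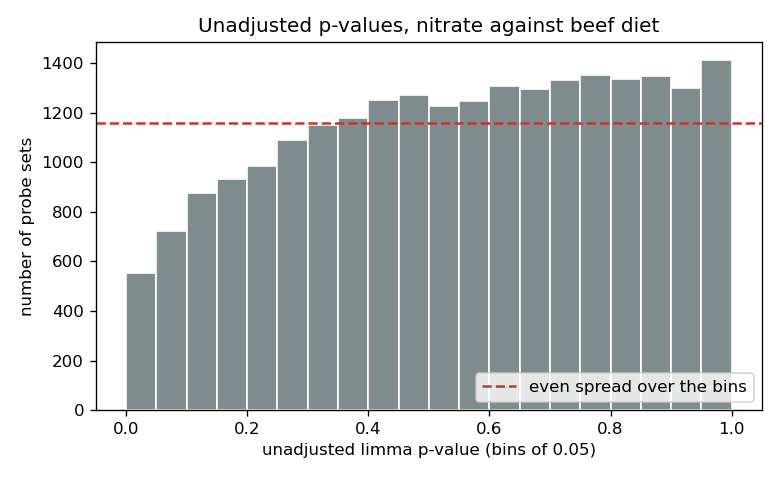
Number of probe sets in each bin of unadjusted limma p-values for the nitrate diet against the beef diet, with the dashed line at 1159 probe sets per bin. The lowest bin holds 552 probe sets and lies below the line.

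The remaining genes picked by the same rule on the higher side were Zfp865, Nat8b, Ptpn1, which dephosphorylates the insulin receptor, Eng, Patz1, Ptp4a3, Adat2, Cnot8, a subunit of the deadenylase complex, and Prb3. Their differences ran from 0.16 for Adat2 to 0.36 for Cnot8, with an interval of 0.08 to 0.63 for Cnot8. On the lower side they were Herpud1, Lcat, which esterifies cholesterol, Pofut2, Erlin2, Stk3, Shoc2, Cflar, Lrrn3 and Lnpk, from -0.14 for Herpud1 to -0.28 for Lcat, with an interval of -0.48 to -0.07 for Lcat. These 24 genes were chosen by small p in the same animals, which favours stable differences, so their stability lends them no support. With 1 animal left out in turn, their differences kept their sign and moved by no more than 1.5 times. Of all 150 named genes 64 turned or moved by more than that without some animal, and 4 of them turned (Ttr, Hmox1, Arc and Ccn3), as did 40 of the 41 list scores, of which 21 turned. For genes given below that did so, the value nearest to or past 0 follows theirs. 5 probe sets differed by more than 0.5 log2 units in their group means, and they are named here after their values were seen. Sncg was higher by 0.72 (95% interval -0.15 to 1.59), Vwa3a by 0.51 (0.03 to 1.00) and RGD1309362 by 0.51 (0.12 to 0.90). The choroid plexus potassium channel gene Kcnj13 had a difference of -0.50 (-1.32 to 0.31), which was -0.06 without beef replicate 10, and the unnamed probe set TC0400000481.rn.2 one of -0.80 (-2.61 to 1.01), with SDs above 2 in both diets. All of them had an adjusted limma p of 0.9999.

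Nitrate can be reduced in the body to nitrite and nitric oxide, so the genes of nitric oxide and cyclic GMP signalling formed 1 of the lists fixed beforehand. 17 of its 39 measured genes were higher and 22 lower on nitrate, and the mean of the list differed by -0.01 log2 units (95% interval -0.04 to 0.02; permutation p = 0.555; n = 10 per diet). The neuronal synthase Nos1 read 7.57 ± 0.24 (SD) on beef and 7.47 ± 0.17 on nitrate, the inducible synthase Nos2 4.61 ± 0.19 and 4.55 ± 0.21, and the endothelial synthase Nos3 6.14 ± 0.21 and 6.23 ± 0.25. Their differences of -0.10, -0.05 and 0.09 were -0.06 without beef replicate 9, -0.01 without beef replicate 10 and 0.04 without nitrate replicate 10. Nos2 lay below the 25th percentile of probe set means, 5.575, and detection was not examined, so its small difference says little about its expression. The smallest unadjusted p of the list belonged to Prkg2, a cyclic GMP-dependent kinase, with a difference of -0.22 (95% interval -0.39 to -0.04; p = 0.0185). It was followed by Irag1, a substrate of such kinases, at 0.15 and the arginine transporter gene Slc7a2 at -0.14. Irag1 also lay below that percentile. 0 of the 39 passed over all genes, 0 passed adjusted over the list alone with limma, and 1 had an unadjusted p under 0.05.

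**Figure D2:**
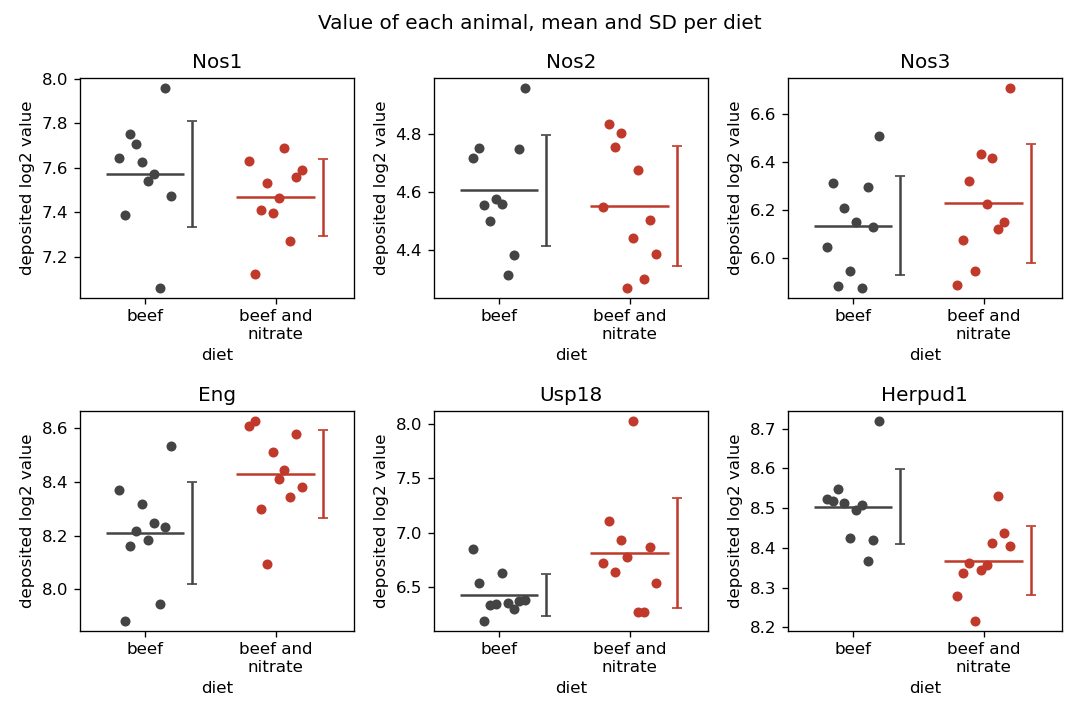
Deposited log2 value of each animal on the beef diet (dark points) and on the beef and nitrate diet (red points), with the diet's mean as a line and its SD as a bar, n = 10 per diet. Nos1, Nos2 and Nos3 overlap between diets, and Eng, Usp18 and Herpud1 differ by 0.22, 0.38 and -0.14 in their means without passing the adjusted threshold.

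None of the genes named beforehand for mood disorder, plasticity and stress passed the threshold. Bdnf, a neurotrophin, differed by 0.09 (95% interval -0.17 to 0.35; 0.02 without beef replicate 2), the calcium channel gene Cacna1c by -0.07 (-0.21 to 0.08; -0.03 without nitrate replicate 2), Ank3, which anchors channels at the axon initial segment, by -0.05 (-0.14 to 0.03), and Hmox1, a haem-degrading enzyme, by -0.01 (-0.17 to 0.16; 0.02 without nitrate replicate 1). The activity-regulated genes Fos and Arc differed by 0.04 (-0.13 to 0.21; 0.01 without beef replicate 10) and 0.01 (-0.24 to 0.26; -0.03 without beef replicate 2). Ttr, the thyroxine carrier made by choroid plexus, differed by -0.08 (-1.17 to 1.01), although 9 of 10 nitrate animals lay above the beef median. Its sign rests on beef replicate 10, which read 13.19, and without that animal the difference of Ttr was 0.38. Each of these had an adjusted limma p of 0.9999. The list of bipolar disorder risk loci had 9 of 23 measured genes higher, led by Itih3 at -0.18 and Erbb2 at -0.14 (-0.07 without beef replicate 10), and the immediate early genes 17 of 31, led by Egr2 at -0.21 and Nr4a1 at 0.18 (0.11 without nitrate replicate 2). In the list of neurotrophins, CREB and plasticity, 18 of 32 genes were higher, with Igf1 at 0.21 and Prkacb at -0.15 (-0.10 without nitrate replicate 2).

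Across the 41 gene lists fixed beforehand, with 997 distinct measured genes, 0 genes passed over all genes and 0 passed adjusted over the list alone with limma, while 21 had an unadjusted p under 0.05. The smallest p adjusted over a list alone was 0.155, for Eng among the endothelial genes. Endothelial genes and blood genes were the 2 lists that shifted by limma's camera with a preset correlation of 0.01, both towards higher values on nitrate. Both calls were lost with limma's camera at an adjusted p = 0.918 with an estimated correlation, where 0 of the 41 lists passed. 14 of 18 measured endothelial genes were higher, among them Eng, a co-receptor of vascular endothelium (0.22 ± 0.08, SE), Esam, an endothelial adhesion molecule (0.11 ± 0.06), and Cldn5, a tight junction protein of the blood-brain barrier (0.17 ± 0.12, and 0.08 without beef replicate 3). 14 of 17 blood genes were higher, among them Alas2, the erythroid enzyme that starts haem synthesis (0.23 ± 0.09), and Pf4, a platelet chemokine (0.17 ± 0.08), while Epb42, a red cell membrane protein, differed by -0.16 ± 0.09. Of the measured genes, 6 of 17 blood and 11 of 18 endothelial genes lay above the median probe set. Epb42 lay below the 25th percentile of probe set means, 5.575.

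Both lists had an adjusted limma camera p of 0.0486 with the preset correlation. Fry passed 0 lists for a shift in 1 direction and 0 for change in either direction, and the smallest adjusted fry p for a shift in 1 direction was 0.975. The mean score of the endothelial genes differed by 0.06 log2 units (95% interval -0.04 to 0.16; permutation p = 0.218; n = 10 per diet; 0.04 without beef replicate 3), above the beef median in 7 of 10 nitrate animals, and that of the blood genes by 0.09 (-0.03 to 0.21; permutation p = 0.144), above it in 8 of 10. 0 lists passed by the permutation test of scores, with a smallest adjusted p of 0.975. The endothelial call ended without any 1 of 11 animals (beef replicates 2, 3, 8 and 10, nitrate replicates 1, 3 and 5 to 9), with adjusted camera p-values from 0.00069 to 0.46 over the 20 animals left out in turn. The blood call ended without any 1 of 12 (beef replicates 1, 3, 5, 7 and 8, nitrate replicates 1, 2, 3, 5, 7, 9 and 10), with 0.00208 to 0.46.

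**Figure D3:**
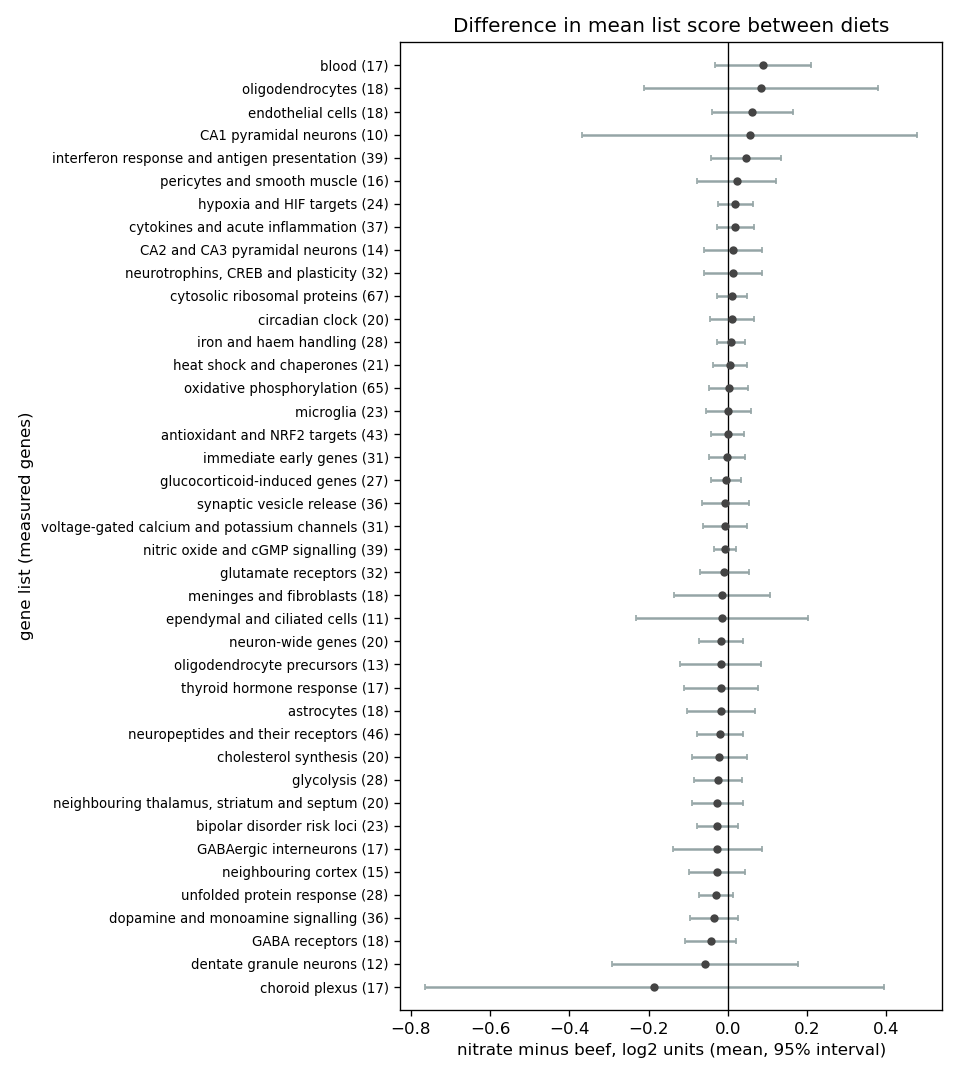
Difference in the mean score of each of the 41 gene lists, nitrate minus beef, in log2 units, with 95% intervals, n = 10 per diet and the number of measured genes in parentheses. Every interval includes 0, and the interval of choroid plexus, from -0.76 to 0.39, is the widest.

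With all 20 animals, the other cell type lists showed no shift that passed. 16 of 18 oligodendrocyte genes were higher on nitrate, such as Tspan2 at 0.19 (0.12 without beef replicate 2) and the myelin transcription factor gene Myrf at 0.15, with a score difference of 0.08 (95% interval -0.21 to 0.38) and an adjusted camera p of 0.129. The score difference was 0.02 without beef replicate 2 and 0.15 without nitrate replicate 4, and Myrf was at 0.08 without beef replicate 2. The oligodendrocyte list passed without any 1 of 6 animals (beef replicates 1, 4 and 6, nitrate replicates 4, 6 and 7), with adjusted camera p-values from 5.41e-05 to 0.736 over the 20 animals left out in turn and an adjusted p of at least 0.747 with an estimated correlation in those 6 runs. Among oligodendrocyte precursor genes 6 of 13 were higher, with Bmp4 at -0.28 (-0.15 without nitrate replicate 8) and Olig1 at 0.12. 2 of 18 astrocyte genes were higher, Ntsr2 being at -0.07 and the glycolytic enzyme gene Aldoc at -0.05, and the score differed by -0.02 (-0.10 to 0.07). Without nitrate replicate 4 both Ntsr2 and Aldoc were at -0.02 and the astrocyte score difference was 0.00. Microglial genes were split, 12 of 23 higher, and included Itgam, an integrin of myeloid cells, at -0.29 (-0.56 to -0.02) and Ptprc, a leukocyte phosphatase, at 0.13 (0.01 to 0.26). Ptprc lay below the 25th percentile of probe set means, 5.575. Of the pericyte and smooth muscle genes 11 of 16 were higher, with Notch3 at 0.12 and Tagln at 0.19 (0.12 without beef replicate 3 and 0.31 without nitrate replicate 4), and the score difference of 0.02 was 0.00 and 0.06 without these 2 animals in the same order. Of the genes found in neurons at large 5 of 20 were higher, with Elavl4 and Nefh both at -0.11 (-0.06 without beef replicate 9 and -0.07 without beef replicate 1). Interneuron genes were higher in 9 of 17 cases, with Lhx6 and Sst both at -0.13. Without beef replicate 9 Lhx6 was at -0.05, Sst at -0.08 and the score difference at 0.01 in place of -0.03.

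With all 20 animals no regional list passed either, and single animals stood apart in several of them. CA1 genes were higher for 8 of 10, led by Fibcd1 at 0.22 (0.11 without nitrate replicate 2), with a score difference of 0.06 (95% interval -0.37 to 0.48), and dentate granule genes for 2 of 12, with Npy1r at -0.14 and Lct at 0.17, and a score difference of -0.06 (-0.29 to 0.18). Without nitrate replicate 2 the score differences were -0.04 for CA1 and 0.03 for dentate genes, and camera passed CA1 genes without nitrate replicate 4 (adjusted p = 0.0327; adjusted p = 0.747 with an estimated correlation) and dentate genes without beef replicate 9 (adjusted p = 0.0337; adjusted p = 0.969 with an estimated correlation). CA2 and CA3 genes were higher for 8 of 14, with Rgs14, a marker of CA2, at 0.18 (0.12 without nitrate replicate 2). Genes of the neighbouring cortex were higher for 4 of 15, with Sulf1 at -0.15 (-0.06 without beef replicate 10), and those of neighbouring thalamus, striatum and septum for 6 of 20, with Drd1, a dopamine receptor, at -0.20 (-0.13 without nitrate replicate 10). 3 of 17 choroid plexus genes were higher, with an adjusted camera p of 0.129, and beef replicate 10 alone stood at a score of 2.50 while the other 19 animals lay between -0.40 and 0.24. Without it 13 of 17 were higher and the score difference turned from -0.19 to 0.08. The list passed as lower without beef replicate 4, 7 or 9, with adjusted camera p-values from 0.0337 to 0.0387 and an adjusted p of at least 0.906 with an estimated correlation. Ependymal genes were higher for 3 of 11, with Rarres2 at 0.20, and genes of meninges and fibroblasts for 9 of 18, with Aldh1a2 at -0.11 (-0.06 without nitrate replicate 7).

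**Figure D4:**
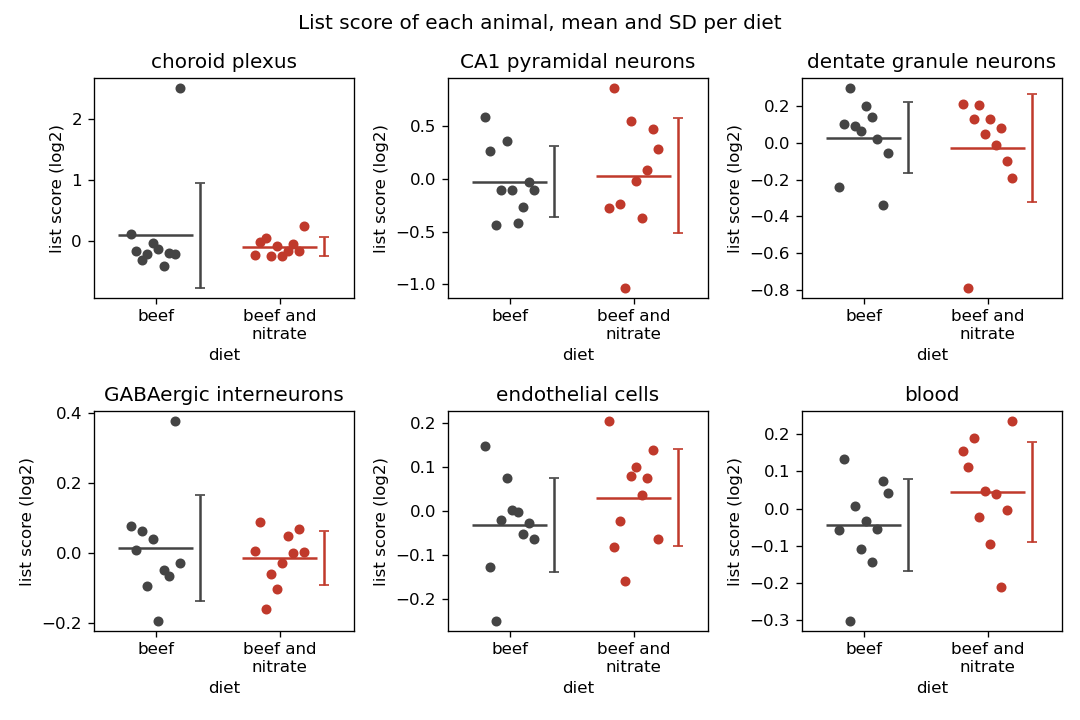
List score of each animal, in log2 units relative to the mean of all 20 animals, for 6 lists on the beef diet (dark points) and the beef and nitrate diet (red points), with the mean as a line and the SD as a bar, n = 10 per diet. Beef replicate 10 stands at 2.50 for choroid plexus and nitrate replicate 2 at -0.79 for dentate granule neurons, while the endothelial and blood scores overlap between diets.

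Among immune and stress lists, interferon response and antigen presentation had 25 of 39 genes higher, 4 of them at an unadjusted p under 0.05, and an adjusted camera p of 0.131. Without beef replicate 1 that p was 0.00595, and the adjusted p = 0.931 with an estimated correlation. Usp18, which restrains interferon signalling, differed by 0.38 (95% interval 0.07 to 0.70), and the interferon regulatory factors Irf7 and Irf9 by 0.24 (0.04 to 0.44) and 0.27 (0.04 to 0.50). The highest Usp18 value, 8.02, came from nitrate replicate 6 and the next nitrate animal read 7.10, and without that animal the difference of Usp18 was 0.25. Cytokines and acute inflammation had 22 of 37 genes higher, with Tgfb1 at -0.20 (-0.34 to -0.06) and Casp1 at 0.17 (0.02 to 0.33). The unfolded protein response had 10 of 28 genes higher, and 3 genes of the endoplasmic reticulum led it: Herpud1 at -0.14, the chaperone Hspa5 at -0.10 (-0.07 without beef replicate 3) and the disulphide isomerase Pdia3 at -0.09, with an adjusted camera p of 0.129. Heat shock and chaperones had 11 of 21 higher, led by Dnajb5 at 0.10 and Cryab at 0.18 (0.12 without beef replicate 2), and glucocorticoid-induced genes 15 of 27, with Mertk at 0.13 (0.08 without nitrate replicate 6) and Klf15 at -0.11.

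No metabolic list passed. Glycolysis had 4 of 28 genes higher, with the lactate transporter gene Slc16a7 at 0.15 and the aldolase gene Aldoa at -0.08, a score difference of -0.02 (95% interval -0.09 to 0.04) and an adjusted camera p of 0.21. Oxidative phosphorylation had 32 of 65 higher, with Atp5mg at 0.10, and cytosolic ribosomal proteins 46 of 67, with Rps20 at 0.08. Without beef replicate 6 camera passed glycolysis as lower and ribosomal proteins as higher, both at an adjusted p of 0.0329, and at an adjusted p = 0.75 and an adjusted p = 0.81 with an estimated correlation. Antioxidant and NRF2 targets had 18 of 43 higher, with Txnrd1 at 0.11 and Me1 at -0.10, and iron and haem handling 16 of 28, with Steap2 at -0.16 and Cp at 0.11 (0.06 without beef replicate 8). Hypoxia and HIF targets were split evenly, 12 of 24 higher, with Adm, a vasodilator peptide, at 0.20 (0.06 to 0.35) and the carbonic anhydrase gene Car9 at 0.14 (0.03 to 0.25). Cholesterol synthesis had 8 of 20 higher, with Lss at 0.10 and Nsdhl at -0.16 (-0.09 without nitrate replicate 2), the thyroid hormone response 8 of 17, with Thrb at -0.17, and the circadian clock 13 of 20, with Per2 at 0.08 (0.04 without beef replicate 8).

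Lists of neuronal signalling also stayed short of the threshold. GABA receptors had 6 of 18 genes higher, with the GABA transporter gene Slc6a11 at -0.13 and Abat, which breaks GABA down, at -0.08 (-0.04 without nitrate replicate 4), and a score difference of -0.04 (95% interval -0.11 to 0.02). Glutamate receptors had 17 of 32 higher, with Grin2d at -0.24 (-0.46 to -0.02), a value of 7.50 for it in beef replicate 9, and -0.15 without that animal. Dopamine and monoamine signalling had 14 of 36 higher, with the noradrenaline transporter gene Slc6a2 at 0.17 (0.03 to 0.31) and the serotonin receptor gene Htr2a at -0.23 (-0.52 to 0.05; -0.15 without beef replicate 9). Neuropeptides and their receptors had 16 of 46 higher, with Tac3 at 0.24 (0.15 without nitrate replicate 2) and Ntsr1 at -0.20 (-0.10 without beef replicate 2), voltage-gated calcium and potassium channels 17 of 31, with Kcnd2 at 0.09 and Kcnd3 at -0.21, and synaptic vesicle release 14 of 36, with Sv2c at 0.15 and Syt2 at 0.15.

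Among the strongest loadings of the 2 largest axes of variation were markers of choroid plexus and hippocampal fields. By the rule for single animals given below, nitrate replicate 2 stood apart on the second axis and no animal did on the first. The first principal component held 19.6% of the variance, and its highest loadings included the choroid plexus genes Ttr, Clic6, Kl and Kcnj13. Beef replicate 10 stood at 29.5 on it, the next animal, beef replicate 2, at 13.6, and nitrate replicate 1 at the other end at -21.9. All 17 choroid plexus genes were highest in beef replicate 10, but beef replicate 2 had a choroid plexus score of -0.17. The interquartile range of an array's values was narrowest in beef replicate 10, at 3.01, and widest in nitrate replicate 1, at 3.34. It was 3.05 in beef replicate 2. Whether the first component follows this spread of the arrays was not tested. The second component held 12% of the variance and set CA1 genes such as Pou3f1 and Ndst4 against the dentate gene C1ql2. Nitrate replicate 2 stood at 28.8 on the second component. Components 3, 4 and 5 held 8.51%, 6.76% and 5.54%. None of the 5 differed between diets by the permutation test, whose unadjusted p ran from 0.407 to 0.943 and whose adjusted p was 0.943 for each (n = 10 per diet).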

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

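Of the tests in this part, those of choroid plexus tissue, a noisy array and uneven field shares were chosen after the result was seen. The test of the diet on the CA1 minus dentate score was chosen before its own result, but after the pattern it addresses was seen. Values of single animals were compared with the other 9 animals of the same diet, and an animal is listed where its gap to the nearest other animal was a large part of the diet's range. This was tested in 398 sets of 10 values, of which 38 gave such an animal, against 20 that chance gives at 1 in 20. The sets are not independent, since genes of a list move together.

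Choroid plexus genes stood far above the rest in beef replicate 10. Its choroid plexus score was 2.50 against 0.11 for the next beef animal, and Ttr read 13.19, Kcnj13 9.58, Slc4a5 8.63 and Prlr 7.82, where the next beef animals read 10.35, 5.71, 6.60 and 4.74. This array was the highest of the 20 for all 17 measured list genes, and the median deviation of the list was 2.44 log2 units. The highest of 10000 random lists of matched expression reached 0.37, which argues against scattered noise as the source of this rise. That comparison does not measure the noise of the array itself. Choroid plexus tissue carried along in the dissection is a candidate explanation that these 17 genes fit, and no biological explanation was tested, since the animal shares its diet with 9 others. In the other 19 animals 3 of the 17 genes lay above the median probe set, and 1 is held by another list. The same array had the lowest mean correlation with the other arrays, 0.988. It also had the widest interquartile range of deviations from the probe set medians, 0.27 against 0.25 in nitrate replicate 2. General noise of the array is therefore not excluded. Its other values apart were a meninges and fibroblasts score of 0.38, Sulf1 at 6.99, Herpud1 at 8.72, Nat8b at 6.44 and Adat2 at 7.51.

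CA1 genes were high and dentate genes low in nitrate replicate 2, with the same direction in beef replicate 1. Nitrate replicate 2 had a dentate score of -0.79 against -0.19 for the next nitrate animal and stood at 28.8 on the second component, and against the mean of the other 19 animals C1ql2 differed by -2.33 log2 units, Prox1 by -1.76, Pou3f1 by 1.57 and Wfs1 by 1.35. Over the 20 animals the CA1 and dentate scores, the 1 pair of scores related in this way, had Pearson r = -0.653 (permutation p = 0.00178, Benjamini-Hochberg 0.00712 over the 4 sets of animals) and Spearman rho = -0.66 (p = 0.00185), r = -0.503 (p = 0.135) within beef, r = -0.712 (p = 0.0245) within nitrate, and r = -0.496 (p = 0.0351) without nitrate replicates 2 and 4, which lay farthest from the median CA1 score. An uneven share of the hippocampal fields between samples is a candidate explanation that this negative r is consistent with. Whether the diet contributes stays open. The CA1 minus dentate score differed by 0.11 between diets with an SE of 0.29 (permutation p = 0.706), and nitrate replicates 2 and 4 went opposite ways, with CA1 scores of 0.85 and -1.03. A difference smaller than its SE had been set beforehand as the mark against the diet, which was the wrong bound, since a spread this wide can meet it without excluding the diet.

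Other values of these and further animals are given without explanation. In nitrate replicate 2 the neighbouring cortex score was -0.19, Kcnd2 read 12.07, Nr4a1 9.30 and Prkacb 10.43. In nitrate replicate 4 the pericyte and smooth muscle score was -0.30, with Tagln at 6.76, Ntsr2 at 10.35, Aldoc at 10.43, Shank1 at 11.39, Hspa5 at 10.53 and Arc at 7.27 as the lowest values of that diet and Atp5mg at 11.71 as the highest. In beef replicate 9 the interneuron score was 0.38, Lhx6 read 8.50 and Grin2d 7.50. Beef replicate 2 had an antioxidant score of -0.0918 and Ntsr1 at 6.73, and beef replicate 8 a cytokine score of 0.0720. Nitrate replicate 3 had a channel score of -0.12, nitrate replicate 6 had Usp18 at 8.02 and Foxc1 at 7.11, nitrate replicate 9 had Fos at 5.26 and nitrate replicate 10 had Esam at 7.55. Cldn5 read 8.15 in beef replicate 3 and Abat 10.44 in beef replicate 6.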

How the results depend on the processing

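The runs without beef replicate 10 and nitrate replicate 2 together, those with the choroid plexus and CA1 minus dentate scores as covariates, those that joined an estimated correlation with another setting, and that with sample number without beef replicate 10 were chosen after seeing the data, and all others before. The limma count stayed at 0 in every alternative run. The count at an unadjusted p under 0.05, 552 with all probe sets, was 190 among probe sets above the median, 340 above the 25th percentile and 348 with 1 probe set per gene, where fewer probe sets were tested. With the first residual component as a covariate it was 842. That component came from the residuals of the diet fit, so it leaves every difference between diets unchanged and acts only through the residual spread. What the component follows was not tested. The count lay between 504 and 675 with 1 array left out, and was 563 without both arrays together. The 2 camera calls became 0 with an estimated correlation, by fry, with the residual component and with the choroid and field covariates, and 1 without the replicate 5 animals of both diets (endothelial cells); for the last 3 the cause was not tested. With sample number as a covariate choroid plexus was called too (lower, adjusted camera p = 0.0394; adjusted p = 0.983 with an estimated correlation), 3 lists in all. That direction rests on beef replicate 10: without it, with the same covariate, choroid plexus was higher (adjusted camera p = 0.0597), and the 2 lists called were blood (adjusted p = 0.0189) and interferon response (adjusted p = 0.0392), each at an adjusted p = 0.871 with an estimated correlation. Joined with 10 other settings, an estimated correlation called 0 lists, with a smallest adjusted camera p of 0.918. With 1 array left out, 0 to 5 lists were called with the preset correlation, not always these 2, and 0 with an estimated one: 0 without beef replicate 3 or 8 or nitrate replicate 1, 3, 5 or 9, 1 without beef replicate 2, 5 or 10 or nitrate replicate 2, 7, 8 or 10, 2 without beef replicate 7 or nitrate replicate 6, 3 without beef replicate 1, 4 without beef replicate 4 or 9 or nitrate replicate 4, and 5 without beef replicate 6. The preset correlation also called at least 1 list, and up to 10, in all 20 simulated runs without a diet effect. It called 1 to 16 lists, with a median of 6, in 99 other splits of the animals into 10 and 10. Calls that come and go with 1 animal are therefore no sign of a diet effect. Why a given animal changes the count was not tested. List scores passed 0 tests in the alternatives run for them (replicate block, without the replicate 5 animals, mean of a gene's probe sets, genes above the median, without both arrays and without 1 array), and components 0 in theirs (unit variance, probe sets above the median, without the replicate 5 animals and replicate block). The replicate numbers were not treated as pairs, since the labels do not say what they stand for. 9 of 10 same-numbered animals have consecutive sample numbers, so a shared time or handling stays possible. The deviations of same-numbered animals correlated between -0.096 and 0.33, with a mean of 0.059 against -0.0065 for other pairings, 4 of 10 lay above 0.1, and 1 of 10 nitrate animals correlated best with its own number. With the replicate block the counts were 0 probe sets (683 at an unadjusted p under 0.05), 2 lists, 0 scores and 0 components. Of 5035 values of 150 named genes under alternatives, 5005 kept their direction and 0 passed the threshold. Of 1311 list shifts 1204 kept it and 47 passed, and of 1024 score differences 939 kept it and 0 passed. For named genes, some settings leave the log2 difference unchanged by construction, so a kept direction there is no test. These were the replicate block, the filters on dim probe sets, 1 probe set per gene, the variance prior, the plain test and the residual component. The score difference is likewise fixed under the replicate block. Signal over background was not examined.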

Other observations

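Of the tests in this part, the one with an estimated correlation as an explanation of the list calls was chosen after the result was seen, as were the relation of the third component to sample number within diets, the genes with separate clusters of values and the interneuron genes of 1 animal. The splits of the animals and the test of red cell genes were chosen before their own results. The red cell test and the use of splits for the list calls address calls that had already been seen.

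8 of the 17 measured interneuron genes were highest of the 20 animals in beef replicate 9. Htr3a, a serotonin receptor of a class of interneurons, was higher there by 1.17 log2 units than the mean of the other 19 animals, the interneuron transcription factor gene Lhx6 by 0.80, Sst by 0.60 and the vesicular GABA transporter gene Slc32a1 by 0.52, while Gad2, Npy and Pvalb differed by 0.08, 0.05 and -0.01 in the same animal.

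2 probe sets split the animals into separate clusters, by a gap of more than 1 log2 unit with at least 4 animals on each side. The unnamed probe set TC0400000481.rn.2 read 4.84 to 5.28 in 8 animals, 3 on beef and 5 on nitrate, and 8.87 to 10.24 in the other 12. Amph, which encodes a protein of synaptic vesicle endocytosis, read 7.46 to 8.31 in 5 animals, 2 on beef and 3 on nitrate, and 9.60 to 10.43 in the other 15.

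The sample number in the descriptions, whose meaning is not given in the sources used here, was related to the third principal component, 1 of 5 components tested. Over the 20 animals Pearson r was 0.549 (permutation p = 0.0129, Benjamini-Hochberg 0.0646 over the 5) and Spearman rho 0.564 (p = 0.0110), so the relation did not pass the adjustment. Within beef r was 0.439 (permutation p = 0.211), within nitrate 0.716 (p = 0.0212), and without replicate 1 of both diets, farthest from the median number, 0.742 (p = 0.00046). In limma with diet in the model, 2 probe sets were associated with sample number at an adjusted p under 0.05: Wdr35, a gene of cilia, at -0.13 log2 units per 10 numbers (adjusted p = 0.0329) and Rhebl1, a small GTPase gene, at 0.15 (adjusted p = 0.0267).

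The count of 552 probe sets at an unadjusted p under 0.05 was no excess over chance. It lay below the 1159 of an even spread and below the median of 989 over the 99 other splits. 94 of 100 splits of the 20 animals into 10 and 10, the real one included, gave as many or more, and the highest of the other splits gave 2934. That split calls several times the real count, which points to a structure of the samples, and what that split follows was not tested. At the adjusted threshold 3 of the 99 other splits gave any probe set and the highest gave 1.

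Endothelial and blood genes were higher on nitrate by limma's camera with the preset correlation, and both calls were lost at an adjusted p = 0.918 with an estimated correlation. 92 of the 100 splits gave as many as the 2 called lists, with up to 16 in another split, so chance cannot be excluded. Genes of a list that vary together between animals are a candidate explanation for the calls, since the smaller unadjusted p of both lists was 0.122 once the correlation was estimated. More residual blood in the vessels stays open. The 8 red cell genes are themselves members of the called blood list, so that their mean difference of 0.11, with an SE of 0.10 (permutation p = 0.284), restates that call and decides nothing. 7 of these 8 and 7 of the other 9 blood genes were higher. Among the 8, Hba-a1, Hbb, Hbb-b1 and Hbb-bs, at 0.19, 0.14, 0.22 and 0.21, all encode haemoglobin chains, so these are not counts of independent genes. A vascular effect of the nitrate diet stays open as well and cannot be told apart from residual blood by these values.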
